A study of Mus musculus with 25 samples.

How the data were processed

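RNA sequencing of mesenteric fat was read for 25 male mice of 3 inbred strains that drank water or 8% fructose for 14 weeks from 7 weeks of age. The labels gave 2 fructose and 4 water mice of C57BL/6J, 5 and 6 of DBA/2J, and 5 and 3 of FVB/NJ. The source label names mesenteric adipose tissue, whereas the protocol text of the same labels speaks of hypothalamus and liver, so the dissection of the fat itself is not described. Libraries came from stranded total RNA after removal of ribosomal RNA. The labels treat each mouse as a separate animal, and each mouse had 3 lane files, which were used as technical runs and not as replicates. All DBA/2J files carry lanes 6 to 8 and all others lanes 2 to 4, so lane set and strain cannot be told apart.

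The submitters' processing notes name HISAT and StringTie on the mm10 genome, without versions. Per the file headers, each deposited table gives a Coverage column, which holds the mean read coverage (a signal) of each gene. It also gives a deposited FPKM column in FPKM. The tests had been designed for TPM, and the deposited column headed TPM was used, but its values are not TPM of the annotated genes in the strict sense. In every file the assembled loci without a gene symbol sum to the whole TPM total on their own, and the annotated genes repeat part of them. Its unit was therefore recorded as other, and the values are called TPM below only after their header. A symbol on several lines of a file was summed, which left 24421 symbols. Assembled loci without a symbol entered no gene test. The 13 protein genes of the mitochondrial genome carry no symbol in the files, so their list was not tested.

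Depth was read from the ratio of the Coverage to the FPKM column. It ran from 0.439 to 11.2 gigabases per mouse, with a median of 5.13. In all 75 lane files the values correlated best with another lane of the same mouse. Values were averaged over the 3 lanes and divided by median-of-ratios factors, which ran from 0.221 to 1.61. The 12348 genes with a mean of at least 1 were tested.

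Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1). One model held 6 group means and a variance trend, all tests were two-sided, and a call was a Benjamini-Hochberg adjusted p under 0.05. The contrasts were fructose against water in each strain and averaged over the 3 strains, the pairwise differences of these effects, an F test of the interaction with 2 degrees of freedom, and the pairwise strain differences on water. Each group mean is given with its SD over mice, and each log2 fold change with its standard error (SE). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

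Gene lists numbering 20 for pathways and 15 for cell types were fixed before the data were examined. Of these, 33 had at least 3 tested genes. The pathway lists were de novo lipogenesis, fructose uptake and breakdown, glycolysis, triglyceride storage and lipolysis, adipocyte identity and adipokines, fatty acid oxidation, cholesterol synthesis, brown and beige fat, oxidative phosphorylation encoded in the nucleus, genes encoded in mitochondria, extracellular matrix, inflammatory cytokines, interferon response, antigen presentation, the unfolded protein response, heat shock proteins, immediate early genes, circadian genes, insulin signalling and cell division. The cell type lists were B cells, T cells, plasma cells, macrophages, lymph node stroma, pancreatic acinar cells, intestinal epithelium, skeletal muscle, smooth muscle, mesothelium, endothelium, fibroblasts with preadipocytes, liver, neurons and red blood cells. Lists were tested with camera of limma at a preset correlation of 0.01, with p adjusted over all lists of a family of contrasts. The same test with an estimated correlation and the fry test stood beside it, as did calls adjusted over the list alone. Marker scores, the mean log2(TPM + 1) of a cell type list, were compared between fructose and water by exact permutation tests, 45 in all.

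The genes named in the report follow a rule that was also fixed before the data were examined. For each fructose contrast these were the 6 largest rises and 6 largest falls among the calls, or the 12 smallest p where fewer than 12 genes passed, leaving out predicted genes without a proper name. Up to 4 members with the smallest p were added from each of at most 6 passing lists. The interaction gave the 8 smallest p and each water contrast the 4 largest rises and 4 largest falls. Slc2a5, Khk, Lep, Adipoq, Fasn, Scd1, Ucp1 and 8 check genes for strain and sex were always read. That cell type lists count as lists in this rule was settled only after a first output with pathway lists alone had been printed. Genes named outside the rule are marked as chosen after their values were seen.

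The procedure was tested on simulated data in which 200 genes were shifted. With the group sizes at hand a shift of 0.5, 1 and 2 on the log2 scale was found for 8.96%, 49.3% and 86.4% of genes in C57BL/6J, for 34.3%, 80.6% and 95.5% in DBA/2J, and for 19.4%, 64.2% and 95.5% in FVB/NJ. False calls numbered 2 to 8 per contrast. A list shifted by 1 was found at an adjusted p of 1.0e-61, with 0 of 128 other list tests called. The simulated noise was independent between genes and had the same spread in all groups. The list result therefore does not test camera on genes that vary together. Nor do the shares found reflect groups of uneven mice, such as DBA/2J water, where the mean correlation with the own group was 0.781 to 0.897.

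Alternatives chosen before the data were examined were values without further scaling, quantile normalization, FPKM, a pseudocount of 0.1, no filter, a mean of at least 5, the lane median, lanes weighted by depth, only the strains compared, marker scores of lymphocytes and acinar cells as covariates, array weights, robust moderation, a threshold of 0.10, and leaving out each mouse. Added after seeing the data were leaving out DBA/2J water mice 1 and 5, a liver score, neuron and smooth muscle scores, 4 marker scores, log2 depth as covariates, and leaving out genes of small and ribosomal RNAs. A list from which a covariate was built has no value under that covariate, which was also decided after seeing the data. Where mice are given numbers, these follow the order of the labels within a group.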

Results

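Mesenteric fat was compared between mice that drank fructose and mice that drank water, separately in C57BL/6J, DBA/2J and FVB/NJ. Strain markers matched the labels. Nnt, a mitochondrial transhydrogenase partly deleted in C57BL/6J, averaged 2.29 TPM there on water against 8.59 in DBA/2J and 7.57 in FVB/NJ. Gpnmb, a macrophage glycoprotein with a nonsense variant in DBA/2J, averaged 0.345 TPM on water in that strain against 9.94 and 6.45 in C57BL/6J and FVB/NJ. Genes of the Y chromosome were expressed, and the group means of Xist, the RNA of the inactive X chromosome, stayed at or under 0.0257. Sequencing depth differed with treatment in DBA/2J. Its fructose mice had 6.14 ± 1.21 gigabases (n = 5) and its water mice 3.12 ± 1.60 (n = 6), with no overlap (exact p = 0.0065), while depth overlapped between treatments in the other strains (exact p = 0.27 and 0.48). In C57BL/6J mean depth differed in the other direction, with 3.48 ± 0.675 gigabases on fructose (n = 2) and 7.01 ± 3.09 on water (n = 4). There the treatments overlapped only through water mouse 3 at 3.38 gigabases, and the exact test had 15 splits. Water mice 2 and 4 of C57BL/6J owed most of their depth to 1 lane file each. These files held 6.03 and 8.32 gigabases, against 0.839 and 1.19 in the shallowest lanes of the same mice. FVB/NJ water mouse 3 was alike, at 8.66 against 1.22. Depth as a covariate was the sum over lanes, whereas gene values weighted the lanes equally.

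**Figure D1:**
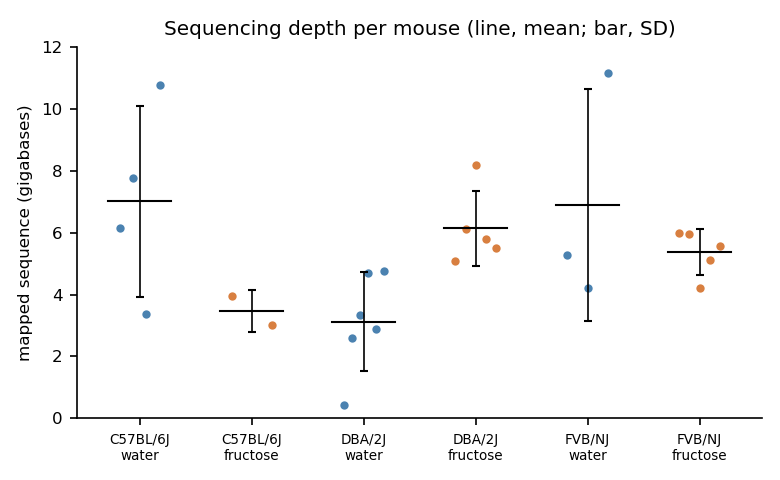
Mapped sequence in gigabases for each mouse, by strain and treatment, with the mean and SD of each group. Fructose and water mice of DBA/2J do not overlap.

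In DBA/2J, the genes with the largest rises on fructose were Saa3, Capg, Gpm6a, Sh3kbp1, Ear12 and Ear3. Saa3, an acute-phase apolipoprotein made by fat and macrophages, was at 17.0 ± 6.33 TPM on fructose (n = 5) against 3.84 ± 1.74 on water (n = 6). Its log2 fold change was 1.91 (SE 0.38, limma adjusted p = 0.014, chr7 46711998 to 46715676, mm10). Sh3kbp1, an adaptor of receptor endocytosis, rose from 0.531 ± 0.644 to 3.75 ± 0.762 TPM (log2 fold change 1.70, SE 0.29, adjusted p = 0.010, chrX 159627272 to 159975920). Capg, which caps actin filaments in macrophages, rose from 5.94 ± 6.71 to 15.3 ± 2.23 (log2 1.77, adjusted p = 0.022), and Gpm6a, a membrane glycoprotein of neurons and mesothelium, from 6.91 ± 5.08 to 18.3 ± 4.07 (log2 1.72, adjusted p = 0.035). Without the atypical water mice 1 and 5, left out after seeing the data, Gpm6a was at 0.79 (adjusted p = 0.087), and its call was lost in 6 of 25 fits that each left out 1 mouse. The eosinophil ribonucleases Ear12 and Ear3, which share coordinates and values, rose by 1.69 on the log2 scale (SE 0.52, adjusted p = 0.047). Scd1, which desaturates fatty acids, rose from 2713 ± 1441 to 5013 ± 943 TPM (log2 1.0, SE 0.28, adjusted p = 0.034).

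In DBA/2J, the named genes with the largest falls on fructose were Lars2, Snord22, Snora78, Rn45s, Snora64 and Mir8101. Lars2, the mitochondrial leucyl-tRNA synthetase whose gene also catches ribosomal RNA reads, went from 162 ± 333 TPM on water to 5.04 ± 0.826 on fructose. Its log2 fold change was -2.70 (SE 0.76, adjusted p = 0.034, chr9 123366940 to 123462664). Rn45s, the ribosomal RNA precursor, changed by -2.34 (SE 0.72, adjusted p = 0.045). Snord22, Snora78 and Snora64, guide RNAs for ribosomal RNA modification, changed by -2.61 (adjusted p = 0.040), -2.45 (adjusted p = 0.013) and -2.09 (adjusted p = 0.027). The microRNA gene Mir8101 changed by -2.09 (adjusted p = 0.029). Of all DBA/2J calls, 22 were genes of small or ribosomal RNA. These transcripts were uneven among the water mice. The libraries of water mice 1 and 5 stood apart, mouse 1 with 0.439 gigabases and mouse 5 with 27.4% of TPM in its 5 largest loci, against 45.5 to 55.8% in the others.

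**Figure D2:**
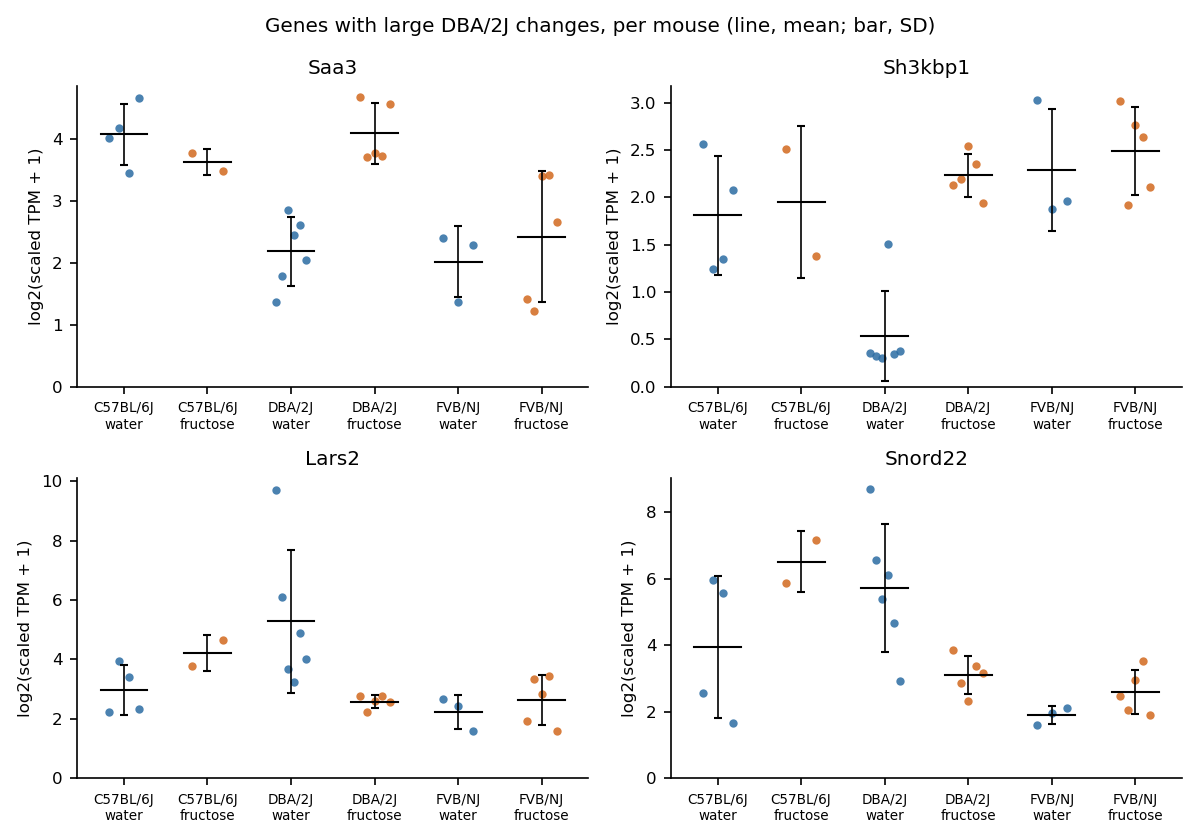
Level of Saa3, Sh3kbp1, Lars2 and Snord22 as log2(scaled TPM + 1) in each mouse, by strain and treatment, with mean and SD. In DBA/2J, Saa3 and Sh3kbp1 were higher on fructose, and Lars2 and Snord22 were lower and scattered widely on water.

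Genes of fibroblasts and preadipocytes were higher on fructose in DBA/2J. Among the 15 members, Dpp4, a surface peptidase of fat progenitors, rose from 5.36 ± 1.77 to 10.9 ± 3.51 TPM (log2 0.91, SE 0.21, adjusted p = 0.020). Dcn, a collagen-binding proteoglycan, rose from 313 ± 112 to 623 ± 201 (log2 1.02, SE 0.28, adjusted p = 0.030). Cd34, a progenitor surface protein, rose by 0.68 (adjusted p = 0.041), and Cd55, a complement regulator, did not pass (0.73, adjusted p = 0.058). The list had 3 calls up and 0 down, 9 and 0 when adjusted over the list alone, and a median log2 fold change of 0.61. Its camera test passed at an adjusted p of 0.0014 and did not with an estimated correlation (adjusted p = 0.52 with an estimated correlation).

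The interferon response was also higher in DBA/2J on fructose. Gbp2, a guanylate-binding protein induced by interferon, rose from 14.7 ± 2.34 to 23.7 ± 4.44 TPM (log2 0.65, SE 0.14, adjusted p = 0.020). The RNA sensor Ifih1 rose by 0.46 (adjusted p = 0.023) and the antiviral Ifit3 by 0.99 (adjusted p = 0.046), while Rsad2 did not pass (0.50, adjusted p = 0.072). Of 18 members 3 were called up and 0 down, and 5 and 1 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.0039, but adjusted p = 0.52 with an estimated correlation). Over genes with a mean of at least 5 the median was 0.22 and the list did not pass (adjusted p = 0.46). Immediate early genes, which switch on within minutes of stimulation, were lower. Klf2 changed by -1.70 (SE 0.40, adjusted p = 0.020), Ier2 by -1.01 (SE 0.23, adjusted p = 0.020) and Klf4 by -0.89 (adjusted p = 0.024), and Dusp1 just missed (-0.77, adjusted p = 0.050). Of 17 members 1 was called up and 3 down, 1 and 6 adjusted over the list alone. The median was -0.33 (adjusted p = 0.012, adjusted p = 0.61 with an estimated correlation). The call was also lost with log2 depth as a covariate (-0.20, adjusted p = 0.10) and with array weights (-0.14, adjusted p = 0.11).

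Liver genes were lower on fructose in DBA/2J as a list but not singly. The median over 16 genes was -1.31 (adjusted p = 0.0074, adjusted p = 0.77 with an estimated correlation), with 0 calls over all genes and 0 adjusted over the list alone. Tat, a tyrosine aminotransferase (-1.91, adjusted p = 0.11), Cps1 of the urea cycle (-1.62, adjusted p = 0.16), and the fibrinogen chains Fga (-1.34, adjusted p = 0.20) and Fgg (-1.41, adjusted p = 0.22) did not pass. The liver score was 4.41 ± 1.06 on fructose (n = 5) and 5.61 ± 2.12 on water (n = 6, exact p = 0.28). Without water mice 1 and 5 the median of the list was 0.02, with log2 depth as a covariate it was -0.15 (adjusted p = 0.66), and without mouse 1 or mouse 5 alone the list lost its call (adjusted p = 0.094 and 0.16).

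In DBA/2J limma called 1089 of 12348 genes, 548 higher and 541 lower on fructose, among 3686 at an unadjusted p under 0.05. Without further scaling the count was 327, with 321 higher and 6 lower, so the even split held only with scaling between mice. Of the 1089 calls with scaling, 147 changed by more than 1 on the log2 scale. The count moved from 64 to 2036 when 1 mouse was left out (64 and 65 without fructose mice 3 and 2, 2036 without water mouse 5), and from 38 (water mice 1 and 2) to 3008 (5 and 6) when a pair of water mice was left out. With log2 depth as a covariate, added after seeing the data, 3 genes were called and no gene named above for DBA/2J kept its call. Some folds changed little, at 1.57 (SE 0.43) for Saa3, 1.52 (SE 0.34) for Sh3kbp1, 1.51 (SE 0.50) for Capg and 0.72 (SE 0.24) for Cd34, with larger SE than before. Others shrank, to -0.83 (SE 0.51) for Lars2, -0.68 (SE 0.54) for Rn45s and 0.75 (SE 0.50) for Ear12. The 3, picked by that fit and so chosen after their values were seen, were the proteasome gene Psmb5 (-0.93, adjusted p = 0.032), the class I gene H2-Q5 (1.40, adjusted p = 0.032) and the tropomyosin Tpm3 (1.49, adjusted p = 0.012). The main fit shared 1 estimate of spread over all 6 groups. DBA/2J water mice were less alike, with a mean correlation with the own group of 0.781 to 0.897. In the other groups it was 0.947 to 0.979. The adjusted p values given for DBA/2J therefore rest in part on the spread of the other strains. With only DBA/2J mice in the fit 13 genes were called, Saa3 and Sh3kbp1 among them. Saa3, Sh3kbp1 and Snora78 kept their calls in all 25 fits that each left out 1 mouse, while Ear12 and Ear3 lost theirs in 21, Ifit3 in 19 and Rn45s in 13 of them. Cd34 and Snord22 lost the call in 7, Lars2 and Scd1 in 6, Dcn in 5, Snora64 and Mir8101 in 4, Ifih1 in 3, and Capg, Dpp4, Gbp2, Ier2, Klf2 and Klf4 in 2. Scd1 also lost it without a filter on low values (adjusted p = 0.56). Without water mice 1 and 5, with fewer mice tested, calls were lost although the folds stayed near for Capg (1.49, adjusted p = 0.051), Dcn (0.85, adjusted p = 0.067) and Snord22 (-2.15, adjusted p = 0.076). They were lost with smaller folds for Rn45s (-1.51), Snora64 (-1.45), Klf4 (-0.59), Ear12 and Ear3 (0.84), Gpm6a (0.79) and Ifit3 (0.54). Apart from Tpm3, of the genes named for DBA/2J only Snora78 had an effect that differed between strains by the F test of the interaction (adjusted p = 0.015).

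**Figure D3:**
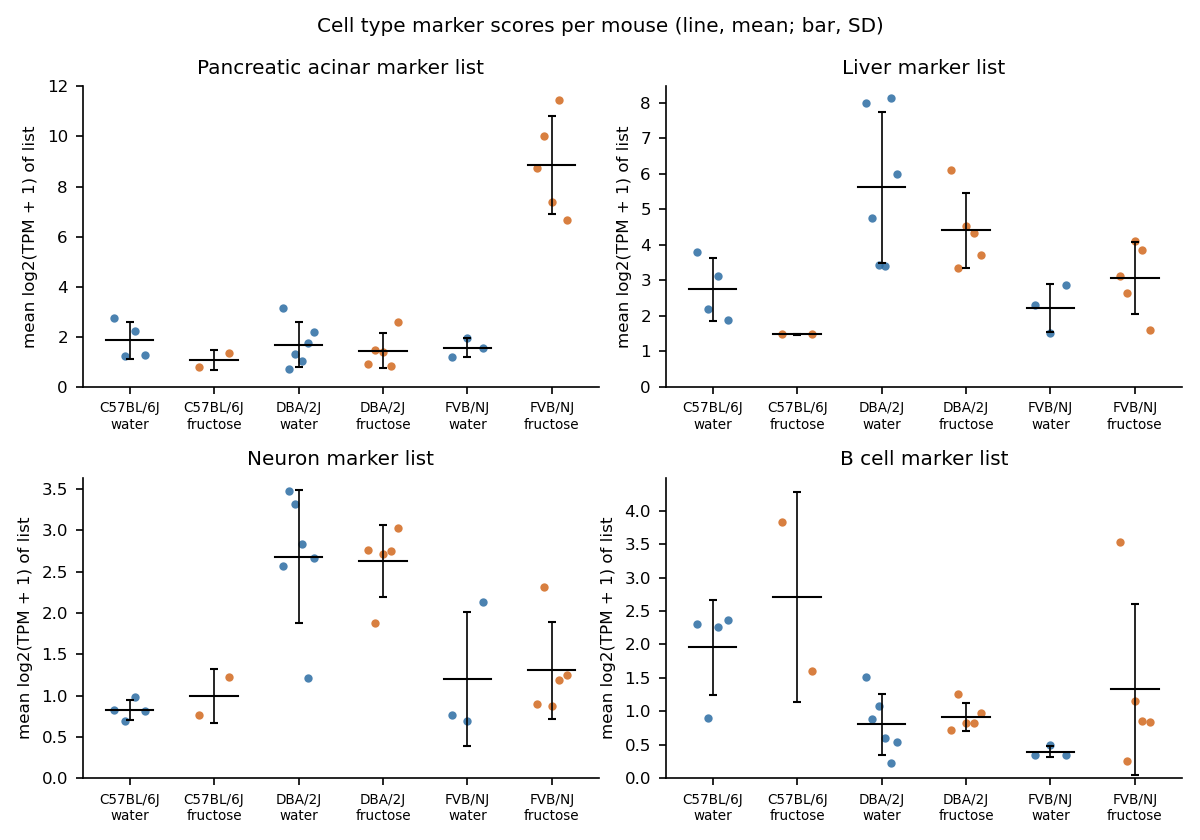
Mean log2(TPM + 1) of the pancreatic acinar, liver, neuron and B cell marker lists in each mouse, by strain and treatment, with mean and SD. The acinar score separated the FVB/NJ fructose mice from all other groups.

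In FVB/NJ, fructose mice carried digestive enzyme transcripts of the exocrine pancreas at levels far above those of water mice. Amy2a5, pancreatic amylase, was at 3936 ± 4898 TPM on fructose (n = 5) against 4.11 ± 1.80 on water (n = 3). The log2 fold change was 8.41 (SE 0.94, limma adjusted p = 3.9e-06, chr3 113249178 to 113356520). Pnlip, pancreatic lipase, was at 2240 ± 2880 against 3.71 ± 2.13 (log2 7.97, SE 0.87, adjusted p = 3.0e-06, chr19 58670365 to 58681788). The proteases Ctrb1, Cela2a, Cpa1 and Prss2 rose by 8.17, 8.09, 7.71 and 7.69 on the log2 scale. Rnase1, a secreted ribonuclease, rose from 0.416 ± 0.289 to 376 ± 461 (log2 7.17, SE 0.62, adjusted p = 8.0e-07). All 19 tested acinar genes were called, also adjusted over the list alone, with a median log2 fold change of 7.41 (adjusted p = 1.4e-158, adjusted p = 9.3e-05 with an estimated correlation). The acinar score was 8.85 ± 1.95 on fructose and 1.57 ± 0.384 on water (exact p = 0.018, the smallest possible, and 0.29 after adjustment over the 45 marker tests).

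Pancreatic transcripts varied widely among the FVB/NJ fructose mice. Pnlip ranged from 233 to 7145 TPM in these 5 mice, from 1.58 to 5.83 in the 3 FVB/NJ water mice and from 0.219 to 11.3 in the mice of the other strains. In scaled TPM, the acinar genes of a fructose mouse summed to 0.256 to 7.50% of the nominal TPM total. Scaling between mice changed that total, so these are not shares of a mouse's own transcripts. Annotated genes also sum to far less than the nominal total. In the lanes of fructose mouse 4, which had the highest acinar score, they summed to 131458 to 145328 TPM before scaling (scaling factor 0.446). The acinar part of the annotated signal was not computed.

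Heat shock proteins, the chaperones of protein folding, were lower on fructose in FVB/NJ. Hsph1, a large co-chaperone, fell from 11.5 ± 1.31 on water to 5.44 ± 1.74 TPM on fructose (log2 -1.0, SE 0.21, adjusted p = 0.023, chr5 149616845 to 149636315). Its call was lost in 5 of 25 fits that each left out 1 mouse, with quantile normalization (-0.94, adjusted p = 0.063), without further scaling (-1.41, adjusted p = 0.58) and with only FVB/NJ mice (-0.99, adjusted p = 0.45). Dnaja1 (-0.59, adjusted p = 0.12) and Hsp90aa1 (-0.64, adjusted p = 0.20) did not pass, nor did Hspd1 (-0.68, adjusted p = 1). The list of 14 had 0 calls up and 1 down, 0 and 4 adjusted over the list alone. Its median was -0.54 (adjusted p = 2.6e-14, adjusted p = 0.0016 with an estimated correlation). With the lymphocyte and acinar scores as covariates the median was -0.05 and the list did not pass (adjusted p = 0.78). The other gene lower on fructose was Tra2a, a splicing factor, from 10.0 ± 0.470 to 5.82 ± 0.847 TPM (log2 -0.70, SE 0.12, adjusted p = 0.0034). Its call was lost without further scaling (-1.13, adjusted p = 0.58) and with only FVB/NJ mice (-0.69, adjusted p = 0.078).

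Genes of nuclear-encoded oxidative phosphorylation were slightly lower in FVB/NJ on fructose (median of 35 genes -0.25, adjusted p = 2.1e-09, adjusted p = 0.52 with an estimated correlation). This rested on water mouse 1, whose mean level was 6.60 against 5.52 and 5.90 in the other water mice, and without it the median was 0.055 (adjusted p = 0.38). Red blood cell genes were lower too (5 genes, -0.73, adjusted p = 1.2e-06, 0 up and 1 down adjusted over the list alone, adjusted p = 0.33 with an estimated correlation). There Alas2, the first enzyme of heme synthesis in red cells, did not pass alone (-0.87, adjusted p = 0.21). B cell genes were higher (9 genes, 0.85, adjusted p = 2.3e-06, adjusted p = 0.52 with an estimated correlation), and this list followed fructose mouse 1, whose B cell score was 3.53 against 0.258 to 1.16 in the others. Immediate early genes were lower (-0.27, adjusted p = 1.1e-04, adjusted p = 0.39 with an estimated correlation), without a call when water mouse 1 was left out (-0.16, adjusted p = 0.20). None of these lists had a call over all genes. A further 7 lists passed only at the preset correlation. Lower were the unfolded protein response (-0.21) and triglyceride storage (-0.23), and higher were antigen presentation (0.20), liver (0.95), T cells (0.54), circadian genes (0.12, 1 up adjusted over the list alone) and lymph node stroma (0.32), with an adjusted p between 0.39 and 0.77 with an estimated correlation. T cells, lymph node stroma and antigen presentation followed fructose mouse 1 like B cells, and without it their medians were 0.15, 0.10 and 0.066 with no call (adjusted p = 0.36 or more), while B cells kept a median of 0.38 (adjusted p = 0.022). Triglyceride storage lost its call without water mouse 1 (-0.050, adjusted p = 0.81), and each of the other 3 lists lost it without 1 or more single mice.

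In FVB/NJ limma called 42 genes, 40 higher and 2 lower on fructose, among 328 at an unadjusted p under 0.05. Of the 42, 19 are on the acinar list, and the other rises include further amylases, trypsins and kallikreins. With lymphocyte and acinar scores as covariates limma called 0 genes, with 243 at an unadjusted p under 0.05, and with only FVB/NJ mice in the fit 22 were called. The acinar score separates these groups completely (6.66 to 11.5 against 1.19 to 1.96), so as a covariate it takes the treatment with it. In that fit Tra2a stayed at -0.70 with a larger SE (0.28 against 0.12), and Hsph1 went to -0.10 (SE 0.44).

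In C57BL/6J, with 2 fructose and 4 water mice, no single gene passed. Agpat4, an acyltransferase of phospholipid synthesis, was at 4.26 ± 1.17 TPM on fructose and 2.27 ± 0.524 on water (log2 0.68, SE 0.16, adjusted p = 0.97). Adipoq, the adipokine adiponectin, was at 583 ± 117 against 1005 ± 261 (log2 -0.76, SE 0.37, adjusted p = 0.97). The other genes with the smallest p, all at an adjusted p of 0.97, were Mapk12 (0.59), Snx29 (0.71), Lrrk1 (0.59), Ttc7 (0.58), Hist1h4j (1.22), Tbc1d2b (0.41), Mphosph6 (-0.90), Srp54c (-0.54), Wwtr1 (-0.55), Mrpl41 (-0.62) and Pnpla8 (-0.60). limma called 0 genes, with 545 at an unadjusted p under 0.05 against 617 expected by chance. Without a filter on low values 29 genes were called.

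Some lists differed in C57BL/6J at the preset correlation, with 0 members called over all genes and 0 adjusted over the list alone. Mesothelial genes, which mark the lining of the abdominal cavity, were higher on fructose (13 genes, median 0.75, adjusted p = 4.8e-08, adjusted p = 0.39 with an estimated correlation). Water mouse 2 was low in them (score 2.25 against 3.52 to 3.74), and without it the median was 0.38 (adjusted p = 0.0011). Among them Lrrn4, Krt19, Crip1 and Bnc1 had log2 fold changes of 0.90, 1.0, 0.75 and 0.64. Adipocyte identity genes were lower (19 genes, -0.52, adjusted p = 3.6e-05, adjusted p = 0.52 with an estimated correlation), with the lipid chaperone Fabp4 at -0.72, the lipid droplet protein Cidec at -0.61 and the adipokine Nampt at -0.57. Oxidative phosphorylation genes were lower (35 genes, -0.22, adjusted p = 2.8e-05, adjusted p = 0.71 with an estimated correlation), with Uqcrb at -1.15, and liver genes as well (16 genes, -1.14, adjusted p = 3.8e-04, adjusted p = 0.71 with an estimated correlation). Lower at the preset correlation were also the unfolded protein response (-0.26), triglyceride storage (-0.33), acinar cells (-0.80), endothelium (-0.29), heat shock proteins (-0.23) and extracellular matrix (-0.23), and higher were B cells (0.78), circadian genes (0.38) and T cells (0.62). All of these 9 lists lost their call, at an adjusted p of 0.33 to 0.77 with an estimated correlation. B and T cells rested on fructose mouse 1 (B cell score 3.82 against 1.60 in fructose mouse 2), and without it their medians were -0.41 and -0.14. Apart from the unfolded protein response, the other lists of the 9 also lost their call without 1 or more single mice.

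Lep, the satiety hormone leptin of fat cells, averaged 41.8 ± 10.8 TPM on fructose and 17.6 ± 9.97 on water in DBA/2J without passing (log2 1.35, SE 0.56, limma adjusted p = 0.11). Its log2 fold change was 0.12 in C57BL/6J (adjusted p = 0.97) and 0.88 in FVB/NJ (adjusted p = 1). Khk, ketohexokinase, the first enzyme of fructose breakdown, was at -0.48 in DBA/2J (adjusted p = 0.15), 0.13 in C57BL/6J and 0.36 in FVB/NJ. Fasn, fatty acid synthase, was at 0.27 in DBA/2J (adjusted p = 0.82), 0.16 in C57BL/6J and 0.03 in FVB/NJ, none of which passed. Scd1, called in DBA/2J, was at -0.49 in C57BL/6J and 0.47 in FVB/NJ, and Adipoq was at 0.59 in DBA/2J (adjusted p = 0.13) and -0.20 in FVB/NJ, without a call. The fructose transporter Slc2a5, with group means of 0.057 to 1.27 TPM, and the thermogenic uncoupler Ucp1, with 0.059 to 1.70, were too low to be tested.

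**Figure D4:**
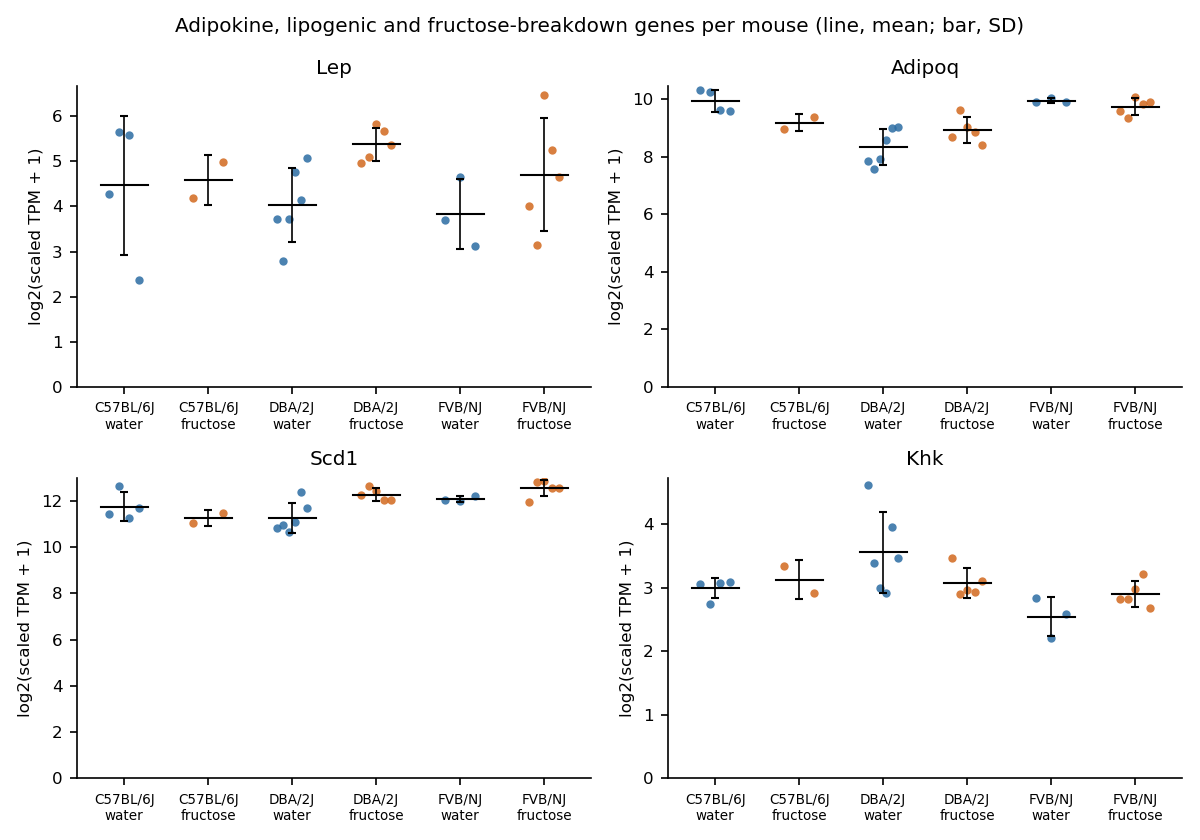
Level of Lep, Adipoq, Scd1 and Khk as log2(scaled TPM + 1) in each mouse, by strain and treatment, with mean and SD. Only Scd1 in DBA/2J passed a test of fructose against water within a strain.

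Averaged over the strains, Rnase1 alone passed (log2 2.29, SE 0.36, limma adjusted p = 0.028, 723 genes at an unadjusted p under 0.05). It is the pancreatic ribonuclease described for FVB/NJ and was named by the rule as the only call. Next were Isl1, a homeobox factor of visceral fat and pancreatic islets (0.94, SE 0.18, adjusted p = 0.068), and the acinar genes Sycn, Pnliprp2, Amy2b, Try5, Clps, Ctrl, Cel and Klk1 at the same adjusted p, with Ctrc and Dmbt1 at 0.076. Isl1 was at 4.20 ± 0.220 TPM on fructose and 1.90 ± 1.07 on water in C57BL/6J, at 2.67 ± 1.01 and 0.574 ± 0.240 in DBA/2J, and at 3.72 ± 1.63 and 1.83 ± 0.583 in FVB/NJ. The acinar list (median 2.13, 1 call, 19 adjusted over the list alone) and the heat shock list (-0.28, 0 calls, 0 up and 3 down adjusted over the list alone) both passed, and both kept an adjusted p of 0.036 with an estimated correlation. The call of Rnase1 was lost in 15 of 25 fits that each left out 1 mouse.

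A further 16 lists passed on average only at the preset correlation, with an adjusted p of 0.26 to 0.71 with an estimated correlation. B cells, T cells, antigen presentation, lymph node stroma, adipocyte identity, the interferon response and insulin signalling lost their call without C57BL/6J fructose mouse 1. Insulin signalling and lymph node stroma each lost it in 12 of 25 fits that left out 1 mouse, adipocyte identity in 7, fibroblasts with preadipocytes in 6 and the unfolded protein response in 1. Liver lost it without DBA/2J water mice 1 and 5 (-0.15 against -0.55, adjusted p = 0.43). Higher on fructose were mesothelium, B cells, circadian genes (3 up adjusted over the list alone), T cells, the interferon response, antigen presentation (1 up adjusted over the list alone), fibroblasts with preadipocytes and lymph node stroma. Lower were oxidative phosphorylation, immediate early genes (2 down adjusted over the list alone), red blood cells, triglyceride storage, liver, the unfolded protein response, adipocyte identity and insulin signalling. Lists that passed the camera test in no fructose contrast were de novo lipogenesis (lowest adjusted p = 0.12 in DBA/2J), fructose uptake and breakdown (0.14 in DBA/2J), glycolysis (0.064), fatty acid oxidation (0.064), macrophages (0.051), inflammatory cytokines (0.064), smooth muscle (0.083), cholesterol synthesis, brown and beige fat, cell division, intestinal epithelium, neurons and plasma cells. Skeletal muscle had only 2 tested genes and was not tested as a list. Inflammatory cytokines in DBA/2J nevertheless had 2 calls up of 8 genes, Saa3 and the monocyte attractant Ccl2 (log2 0.95, SE 0.29, adjusted p = 0.046), the latter named after its value was seen. The list had 4 up adjusted over the list alone, a fry adjusted p of 0.0031, and mean levels of 2.39 to 2.57 in the fructose mice against 1.82 to 2.14 in the water mice, which like depth did not overlap. The fry test asks whether the genes of a list changed, not whether they changed more than other genes. In DBA/2J 3686 of 12348 genes had a limma unadjusted p under 0.05, so the fry result does not set this list apart. The sign of the median, the mean and the test differed in several of the lists without a call, among them de novo lipogenesis in C57BL/6J, where the test pointed down and the median was 0.03.

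The difference between fructose and water mice was not the same in all strains, with the largest differences in pancreatic genes. The F test of the interaction called 70 genes, of which 37 were called higher on fructose in FVB/NJ, 19 are on the acinar list and 31 were called in DBA/2J. The smallest p belonged to Rnase1, Try5, Ctrl, Amy2a2, Amy2a3, Amy2a4, Amy2b and Cela3b, all at a limma adjusted p of 1.0e-04. Among the others, Tpm3, a tropomyosin of the actin skeleton chosen after its values were seen, had log2 fold changes of -0.56, 1.46 and 0.15 in C57BL/6J, DBA/2J and FVB/NJ (adjusted p = 0.0019). Of the genes named for C57BL/6J, Agpat4, Srp54c, Ttc7 and Hist1h4j passed this test, whereas Hsph1 and Tra2a of FVB/NJ did not. With lymphocyte and acinar scores as covariates 1 gene was left, Tpm3 (adjusted p = 0.0088), which was named after that fit.

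In the pairwise differences, 33 genes had a higher effect and 0 a lower effect in FVB/NJ than in C57BL/6J. Against DBA/2J, FVB/NJ had 40 higher and 2 lower, the latter being Pdxdc1 (-0.68, adjusted p = 0.037) and Tpm3 (-1.31, adjusted p = 0.048). Between DBA/2J and C57BL/6J the only call was Tpm3 (2.02, adjusted p = 0.031), named after its value was seen. At a limma unadjusted p under 0.05 this contrast held 2645 genes against 617 expected by chance, and 611 genes had an adjusted p under 0.10. A single call therefore does not show that the effects of these strains differed in 1 gene only. The acinar list differed by 8.19 between FVB/NJ and C57BL/6J and by 7.59 between FVB/NJ and DBA/2J (adjusted p = 2.1e-04 and 0.036 with an estimated correlation). The effect on heat shock genes differed by -0.54 between FVB/NJ and DBA/2J (adjusted p = 0.0011, 0 up and 5 down adjusted over the list alone). The effect on adipocyte identity genes was higher by 0.78 in DBA/2J than in C57BL/6J (adjusted p = 0.013, 4 up adjusted over the list alone), as did fibroblasts with preadipocytes by 0.66 (adjusted p = 0.010) and the unfolded protein response by 0.35 (adjusted p = 0.022, 5 up adjusted over the list alone). These lists, and all others that differed, lost the call at an adjusted p of 0.46 to 0.99 with an estimated correlation. The lists that differed between DBA/2J and C57BL/6J also lost it without 1 or more single mice, C57BL/6J fructose mouse 1 or 2 among them.

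Across genes, the fructose effects of C57BL/6J and DBA/2J correlated at r = -0.29 (jackknife SE over mice 0.25), those of C57BL/6J and FVB/NJ at 0.016 (SE 0.11), and those of DBA/2J and FVB/NJ at -0.13 (SE 0.085). By rank the coefficients were -0.38, 0.33 and -0.15, so r and rank differed for C57BL/6J and FVB/NJ, where 63.4% of all genes shared a sign. Of the 1089 DBA/2J calls, 908 had the opposite sign in C57BL/6J, where 35.4% of all 12348 genes shared a sign. Mean depth on fructose was lower than on water in C57BL/6J and higher in DBA/2J, and its part in these opposite signs was not tested. In C57BL/6J, water mice 2 and 4 owed most of their depth to 1 lane file each. Tra2a, the only gene called in both DBA/2J and FVB/NJ, was lower in both (-0.37, adjusted p = 0.032, and -0.70, adjusted p = 0.0034). It was named because it was the overlap. By chance 0.088 genes would be lower and 1.78 higher in both strains, against 1 and 0 seen, so the overlap in all was not above chance. Genes are not independent replicates, and the strains shared no control mice.

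On water, DBA/2J fat differed from C57BL/6J fat in smooth muscle, nerve, adipocyte and macrophage genes. Gal, the neuropeptide galanin, was at 41.7 ± 26.9 TPM in DBA/2J (n = 6) and 0.477 ± 0.794 in C57BL/6J (n = 4, log2 4.55). Grem1, a BMP antagonist of smooth muscle, was at 55.1 ± 39.0 against 1.09 ± 1.43 (log2 4.47). Retn, the adipokine resistin, was at 41.9 ± 25.1 against 407 ± 158 (log2 -3.38, limma adjusted p = 9.1e-07). The ribonuclease P-like RNA Rprl3 (9.58) and the class II pseudogene H2-Ea-ps (4.89) were the other largest rises, and Rpl29 (-6.00), Rpl21 (-4.42) and Tmem45b (-4.42) the other largest falls. All strains were aligned to the mm10 genome, and the part of alignment in these and the other strain differences on water was not tested. All 10 smooth muscle genes were called higher (median 2.28, adjusted p = 2.9e-06), and 7 of 8 neuron genes (2.01, adjusted p = 2.5e-04). Adipocyte identity genes were lower, with 0 up and 12 down of 19 (-1.12, adjusted p = 1.0e-04), and macrophage genes with 1 up and 10 down of 17 (-0.75, adjusted p = 1.5e-04). The macrophage list includes Gpnmb, which carries a nonsense variant in DBA/2J, and was not tested without it. Each of these 4 lists had an adjusted p of 0.49 with an estimated correlation, and the same calls stood when adjusted over the list alone. The neuron score was 2.68 ± 0.802 in DBA/2J and 0.829 ± 0.120 in C57BL/6J, and the smooth muscle score 6.58 ± 0.884 and 3.84 ± 0.965. Other tissue markers were higher as well. The mean of the 2 tested skeletal muscle genes was 4.11 ± 0.609 against 2.82 ± 0.483, without overlap, and that of the 3 tested intestinal epithelium genes 4.10 ± 1.71 against 2.04 ± 0.455, with overlap and no call for the list (adjusted p = 0.36).

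Liver genes were also higher in DBA/2J than in C57BL/6J on water, with 14 up and 1 down of 16 and a median of 3.38. Water mice 1 and 5 of DBA/2J had the highest liver scores, 7.98 and 8.14 against 3.39 to 5.99 in its other water mice, and without them the median was 2.09 (adjusted p = 0.031). Cholesterol synthesis was higher with 10 up and 0 down of 20 (0.48), and extracellular matrix with 9 up and 1 down of 24. Lower were antigen presentation (0 up and 8 down of 15), endothelium (0 and 9 of 13), red blood cells (0 and 5 of 5, median -1.50), triglyceride storage (0 and 10 of 20), the interferon response (1 and 7 of 18) and B cells (0 and 2 of 9). Adjusted over the list alone, 10 endothelial genes, 11 storage genes and 1 cholesterol gene were lower and 10 matrix genes were higher, with the other counts unchanged. All of these lost the call at an adjusted p of 0.49 to 0.65 with an estimated correlation, and extracellular matrix and B cells also without single mice. limma called 4675 genes in this comparison, 2419 higher and 2256 lower in DBA/2J, among 5828 at an unadjusted p under 0.05. Without further scaling the split was 523 higher and 3807 lower. The lane sets of these strains differ, and with neuron and smooth muscle scores as covariates 785 genes were called.

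FVB/NJ fat had more heat shock transcripts than C57BL/6J fat on water. Of 14 genes 7 were called up and 0 down, 10 and 0 adjusted over the list alone, with a median of 0.98 (adjusted p = 6.3e-08, adjusted p = 0.044 with an estimated correlation). Rarres1, a carboxypeptidase inhibitor induced by retinoids, was at 116 ± 35.4 TPM in FVB/NJ (n = 3) and 0.573 ± 0.0578 in C57BL/6J (n = 4, log2 6.16). H2-Eb1, a class II chain, was at 0.736 ± 0.168 against 85.2 ± 13.5 (log2 -5.62). Rprl3 (8.95), Gdpd3 (4.36) and Fgfbp1 (3.70) were the other largest rises. Rpl29 (-5.85), Cxcl13, a B cell attractant (-3.60), and Rps2 (-3.57) were the other largest falls. limma called 806 genes, 387 higher and 419 lower, among 2665 at an unadjusted p under 0.05. Without further scaling 101 were called, 31 higher and 70 lower. Higher in FVB/NJ were also oxidative phosphorylation (2 up, 6 adjusted over the list alone), red blood cells (2 and 5), mesothelium (1 and 9), de novo lipogenesis (1 and 5), glycolysis (3 and 4), the unfolded protein response (6 and 10, with 1 and 2 down) and smooth muscle (0 calls). FVB/NJ water mouse 1 stood apart in lipogenesis (mean level 7.07 against 4.84 and 5.53) and glycolysis (5.89 against 4.65 and 5.16) as in oxidative phosphorylation. Without it these lists lost their call, at medians of 0.29, 0.32 and 0.073 against 0.79, 0.49 and 0.37 with it. Smooth muscle lost its call without FVB/NJ water mouse 3 (0.28 against 0.98) or C57BL/6J water mouse 2 or 4, and the mesothelium median went from 0.98 to 0.58 without C57BL/6J water mouse 2. Lower were antigen presentation (7 down, 9 adjusted over the list alone with 1 up), B cells (0 and 9), the interferon response (3 and 7) and macrophages (2 and 4). These lists lost their call at an adjusted p of 0.49 to 0.65 with an estimated correlation.

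FVB/NJ and DBA/2J on water differed in fat, blood and liver genes. Alb, serum albumin, was at 9.38 ± 7.81 TPM in FVB/NJ (n = 3) and 804 ± 993 in DBA/2J (n = 6, log2 -5.18), and the urinary protein genes Mup1 (-5.09) and Mup7 (-4.95) and the apolipoprotein Apoa2 (-5.05) were the next largest falls. DBA/2J water mice 1 and 5 lead these liver genes, and without them Alb was at -3.84 (adjusted p = 0.0034). Tmem45b (5.96), Rarres1 (5.85), Rpl21 (4.95) and Gdpd3 (3.64) were the largest rises. Red blood cell genes were higher in FVB/NJ with 5 up of 5 (median 2.58, adjusted p = 7.4e-06), and adipocyte identity genes with 12 up and 0 down of 19 (1.06, adjusted p = 3.9e-04), each at an adjusted p of 0.49 with an estimated correlation. Oxidative phosphorylation (19 up and 1 down), the unfolded protein response (12 and 1), heat shock proteins (8 and 0), triglyceride storage (10 and 2), de novo lipogenesis (7 and 1) and endothelium (8 and 0) were higher in FVB/NJ. Liver (1 up and 14 down), smooth muscle (0 and 9) and neurons (0 and 7) were lower. Adjusted over the list alone, 22 oxidative phosphorylation, 13 unfolded protein response and 8 lipogenesis genes were higher and 1 heat shock gene was lower, with the other counts unchanged. Without FVB/NJ water mouse 1 lipogenesis went from 0.80 to 0.26 (adjusted p = 0.42) and oxidative phosphorylation from 0.56 to 0.27 (adjusted p = 0.089), and endothelium lost its call without any of 3 single mice. The lists from oxidative phosphorylation to neurons lost their call at an adjusted p of 0.49 to 0.65 with an estimated correlation. limma called 5047 genes, 2501 higher and 2546 lower in FVB/NJ, among 6084 at an unadjusted p under 0.05. Without further scaling 3622 were called, 3241 higher and 381 lower.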

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

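Tests chosen only after the result was seen were the acinar response in every strain, the DBA/2J calls kept without water mice 1 and 5, and the lanes shared between strains. The prediction of every other test was written before its result was seen, and the alternatives of the liver, neuron, smooth muscle and depth scores were themselves added after seeing the data.

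Other splits of the same mice were tried for each count of calls. The FVB/NJ fructose count of 42 was reached by 2 of 56 splits, the real one included, with 52 as the highest other. That higher split set fructose mice 1, 2 and 4 against all other FVB/NJ mice. These mice had the highest acinar scores, 8.74, 10.0 and 11.5, against 7.37 and 6.66 in fructose mice 3 and 5. The DBA/2J count of 1089 was reached by 2 of the 100 splits tried, the real one included (highest other 1733). The split with 1733 calls was the real one with water mouse 5 moved to the fructose side, which points to structure among these mice beyond treatment. The rule written beforehand took under 5% of splits as an argument against chance, and the shares in both strains were under it. Another split gave more calls in each strain, however, so chance is argued against but not excluded for either count. For the 70 interaction genes no other split tried gave as many (1 of 100 splits, highest other 35), which argues against chance. On water no other split tried gave as many genes in any contrast, which argues against chance there. The count of DBA/2J against C57BL/6J was 4675 (1 of 100 splits, highest other 3563). That of FVB/NJ against C57BL/6J was 806 (1 of 35 splits, highest other 607). That of FVB/NJ against DBA/2J was 5047 (1 of 84 splits, highest other 4232). These shares of splits were not corrected for the number of counts tested. Chance cannot be excluded for the 1 gene called on average over the strains, since 5 of 100 splits gave as many and the highest other gave 28.

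The effect of fructose differed between strains for 70 genes by the limma F test, for 33 genes between FVB/NJ and C57BL/6J, for 42 between FVB/NJ and DBA/2J, and for 1 between DBA/2J and C57BL/6J, which was Tpm3. At an adjusted p under 0.10 that last contrast held 611 genes. The acinar list gave the largest differences, a median of 8.19 between FVB/NJ and C57BL/6J and of 7.59 between FVB/NJ and DBA/2J. Pancreatic tissue inside the dissected fat requires that the enzymes keep fixed ratios while their level varies from mouse to mouse. Over the 5 fructose mice the spread of these ratios was 0.0881 of the spread of the genes themselves (0.171 against 1.95), so this explanation has the values it needs and is consistent with the data. A difference in sequencing depth is excluded, as 43 genes were called with log2 depth as a covariate, all of the 42 among them, and the depths overlapped. A response to fructose in every strain is excluded, as the mean log2 fold change of the list was -0.236 in DBA/2J and -0.794 in C57BL/6J. A response of FVB/NJ alone was not tested, since it predicts the same groups.

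The count of 1089 genes in DBA/2J was weighed against 3 technical explanations. The atypical libraries of water mice 1 and 5 are excluded as its whole cause, since 1141 genes were called without them, and 7 of the 14 other pairs of water mice left fewer, with 38 without mice 1 and 2 as the lowest. Liver transcripts in the water mice have part of what they need, with 292 genes called when the liver score is a covariate, but 680 of the 1089 stayed called without mice 1 and 5, where the median of the liver list was 0.02. Depth could not be separated from treatment, because 3 genes were called with log2 depth as a covariate and the depths of the groups do not overlap. The median absolute log2 fold change of the 1089 was 0.63 (median SE 0.17) without the depth term. With it, the median change counted in the direction of the first fit was 0.40 (median SE 0.17). For 60.7% of the 1089 the slope on depth among mice of the other strains had the sign of the DBA/2J change, a share that 41 of 100 permutations reached. The permuted shares ran from 9.27 to 92.2% (median 55.1%), so this test decides neither for nor against depth.

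The 4675 genes that differed between DBA/2J and C57BL/6J on water were weighed last. The lane set remains undecided, as 0 lane numbers are shared by these strains. The atypical water libraries are excluded, since 5285 genes were called without them. Gut wall tissue with enteric neurons and smooth muscle remains undecided, as 785 genes were called with those scores as covariates, and a score that separates strains takes strain differences with it. A biological difference of the strains predicts the same groups and was not tested apart from these, and neither was the alignment of all strains to mm10.

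Single mice stood far from the rest of their group in 20 of 200 groups of values tested, where chance flags about 1 in 20 groups, here 10. In the library of DBA/2J water mouse 5 the 5 largest loci held 27.4% of TPM, against 45.5 to 55.8% in the others. The B cell score of C57BL/6J water mouse 2 was 0.894 against 2.26 to 2.36, and its mesothelium score 2.25 against 3.52 to 3.74. Its Khk level was 2.75 on the log2 scale against 3.06 to 3.09. FVB/NJ fructose mouse 1 had high scores of B cells (3.53 against 0.258 to 1.16), T cells (3.18 against 0.597 to 0.975), plasma cells (2.92 against 1.54 to 1.81) and lymph node stroma (4.24 against 2.60 to 3.02), and a low level of Gpm6a (4.14 against 4.88 to 5.11). In DBA/2J fructose mouse 2 the scores of smooth muscle (5.56 against 6.61 to 7.00) and neurons (1.88 against 2.72 to 3.02) were low and that of fibroblasts with preadipocytes was high (5.62 against 5.22 to 5.33). The same mouse was low in Rn45s (10.2 against 11 to 11.3) and Hsph1 (2.81 against 3.38 to 3.54). The mesothelium score of DBA/2J water mouse 5 was 2.76 against 3.42 to 3.77, and the neuron score of FVB/NJ fructose mouse 2 was 2.32 against 0.872 to 1.25. DBA/2J water mouse 1, the shallowest library, was low in the Y chromosome genes Ddx3y (2.69 against 3.31 to 3.66), Kdm5d (0.827 against 1.83 to 2.12) and Uty (1.40 against 2.09 to 2.35). Sh3kbp1 was at 1.51 in DBA/2J water mouse 4 against 0.303 to 0.376 in the other water mice.

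In data outside the gene tests, assembled loci of the mitochondrial chromosome held 0.647 ± 0.178% of TPM in DBA/2J fructose mice (n = 5) and 0.225 ± 0.0973% in water mice (n = 6), without overlap (exact p = 0.0022, the smallest of 462 splits). Divided by the scaling factor of each mouse the shares were 0.555 and 0.342, which overlapped (exact p = 0.11).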

How the results depend on the processing

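No paired analysis was possible because the mouse numbers follow only the order of the labels and link no fructose mouse to a water mouse. In C57BL/6J, with 2 fructose mice, 49.3% of simulated changes of 1 on the log2 scale were found, so 0 calls there do not show that fat did not respond. Depth fell to 0.439 gigabases in 1 mouse and differs with treatment in DBA/2J. Named genes kept their direction wherever they were called, in every setting. Among named genes, settings chosen before the data were examined left 2287 comparisons unchanged, lost 65 calls and gained 65, and leaving out 1 mouse left 4625 unchanged, lost 160 and gained 63. Counts of calls in C57BL/6J and FVB/NJ stayed within 1.5 times except where given here, and FPKM, the lane median, lanes weighted by depth and robust moderation, like leaving out small RNA genes (added after seeing the data), moved no count by more. Where values below differ, the cause was not tested, except that fewer mice or fewer genes were tested where this is the setting itself. List values are median log2 fold changes whose test turned direction, and lists too small or at 0 in a setting have no value there.

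Without further scaling the limma count in DBA/2J was 327 (321 up and 6 down, against 1089), that of the average 39 (against 1), that of FVB/NJ against C57BL/6J on water 101 (31 up and 70 down, against 806), and r between DBA/2J and FVB/NJ was -0.242 (against -0.125). T cells in DBA/2J turned, with a median of 0.26. In this setting the median of all genes moved by 0.20 in C57BL/6J, 0.57 in DBA/2J, -0.41 in FVB/NJ, 0.12 on average, 0.38, -0.62 and -0.98 in the differences of DBA/2J and of FVB/NJ from C57BL/6J and of FVB/NJ from DBA/2J, and on water -0.62 for DBA/2J against C57BL/6J and 0.62 for FVB/NJ against DBA/2J. The water count of DBA/2J against C57BL/6J then split into 523 up and 3807 down, and that of FVB/NJ against DBA/2J into 3241 up and 381 down. With quantile normalization the counts were 1746 in DBA/2J, 8 on average and 149 for the interaction (against 70). A pseudocount of 0.1 gave 0 on average. Without a filter, with more genes tested, they were 29 in C57BL/6J (against 0), 593 in DBA/2J and 10 on average, and the effect on intestinal epithelium between FVB/NJ and DBA/2J was -0.28. With a mean of at least 5 they were 8 on average, 2777 for DBA/2J against C57BL/6J (against 4675) and 3154 for FVB/NJ against DBA/2J (against 5047). With only the strains compared they were 13 in DBA/2J, 22 in FVB/NJ (against 42) and 1487 for FVB/NJ against C57BL/6J. Array weights gave 2724 in DBA/2J, 24 on average, 2810 for FVB/NJ against C57BL/6J, 1067 for the interaction, r = 0.0436 between DBA/2J and FVB/NJ, and 0.45 for liver in DBA/2J. A threshold of 0.10 gave 2378, 15, 1359 and 296 for DBA/2J, the average, FVB/NJ against C57BL/6J and the interaction.

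With lymphocyte and acinar scores as covariates limma called 0 genes in FVB/NJ, 0 on average (507 at an unadjusted p under 0.05), 492 for FVB/NJ against C57BL/6J and 1 for the interaction. In that setting r was -0.224 between C57BL/6J and FVB/NJ (against 0.0157) and 0.454 between DBA/2J and FVB/NJ. Lists that turned in FVB/NJ were triglyceride storage (0.31), oxidative phosphorylation (0.17), antigen presentation (-0.44), lymph node stroma (-0.040), liver (-2.31) and red blood cells (0.33), and on average antigen presentation (-0.12) and lymph node stroma (-0.11). In the difference of FVB/NJ from C57BL/6J these were oxidative phosphorylation (0.32), heat shock proteins (0.18), liver (-1.51) and red blood cells (0.41), and from DBA/2J oxidative phosphorylation (0.059) and liver (-1.06).

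Added after seeing the data, leaving out DBA/2J water mice 1 and 5 gave 0 on average (1161 at an unadjusted p under 0.05), 2272 for FVB/NJ against C57BL/6J, 583 for the interaction, r = -0.0338 between DBA/2J and FVB/NJ, and 0.016 for liver in DBA/2J. A liver score gave 292 in DBA/2J, 24 on average, 3001 for DBA/2J against C57BL/6J and r = 0.00378 between DBA/2J and FVB/NJ. Neuron and smooth muscle scores gave 0 on average, and 785, 442 and 3138 for DBA/2J against C57BL/6J, FVB/NJ against C57BL/6J and FVB/NJ against DBA/2J. With log2 depth the counts were 3 in DBA/2J, 2 on average (Rnase1 and Sycn, named after this fit), 2642, 1244 and 3341 for the same water contrasts in that order and 36 for the interaction, and r was 0.0109 between DBA/2J and FVB/NJ. With 4 scores (lymphocyte, acinar, liver and neuron) they were 66 in DBA/2J, 0 in FVB/NJ (166 at an unadjusted p under 0.05), 0 on average, 62 for DBA/2J against C57BL/6J, 116 for FVB/NJ against DBA/2J and 1 for the interaction (Tpm3, named after this fit), with r = -0.192 between C57BL/6J and FVB/NJ and 0.108 between DBA/2J and FVB/NJ. Under these 4 scores the lists that turned in FVB/NJ were triglyceride storage (0.36), oxidative phosphorylation (0.085), antigen presentation (-0.15), mesothelium (-0.74) and red blood cells (0.55), and on average triglyceride storage (0.092), adipocyte identity (0.042), insulin signalling (0.013), antigen presentation (0.025) and red blood cells (0.043). In the difference of FVB/NJ from C57BL/6J they were heat shock proteins (0.30) and red blood cells (0.48), from DBA/2J oxidative phosphorylation (0.079) and red blood cells (1.14), and on water between FVB/NJ and DBA/2J smooth muscle (0.41) and endothelium (0.017).

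Leaving out 1 mouse at a time, with fewer mice tested, moved the DBA/2J count from 64 to 2036. It was 411, 65, 64, 364 and 567 without fructose mice 1 to 5, and 307, 1842 and 2036 without water mice 2, 4 and 5. The average went from 0 to 31, and was 0 without C57BL/6J fructose mice 1 and 2 and water mice 2, 3 and 4, DBA/2J fructose mice 2, 3 and 5 and water mice 3, 4 and 5, or FVB/NJ fructose mouse 2 and water mice 1, 2 and 3, with 440 to 849 genes at an unadjusted p under 0.05. It was 16 without DBA/2J water mouse 1 and 4, 19, 17 and 31 without FVB/NJ fructose mice 1, 3, 4 and 5. The interaction went from 39 to 341. It was 41 and 39 without C57BL/6J fructose mice 1 and 2, 161 and 157 without water mice 2 and 3, 43 and 46 without DBA/2J fructose mice 2 and 3, 222, 129, 341 and 244 without DBA/2J water mice 1, 4, 5 and 6, and 45 without FVB/NJ water mouse 3. FVB/NJ against C57BL/6J on water went from 404 to 1646, with 435 and 434 without C57BL/6J water mice 2 and 3, 1646 without DBA/2J water mouse 1, and 404 and 405 without FVB/NJ water mice 1 and 3. FVB/NJ fructose stayed at 40 to 51, C57BL/6J at 0, and the other water contrasts at 3500 to 5232 and 3605 to 5645. In C57BL/6J the lists that turned in these fits ranged from -0.41 to 1.85 for B cells, -0.14 to 1.28 for T cells, -0.51 to 0.037 for extracellular matrix and -0.87 to 0.40 for plasma cells, turning without fructose mouse 1 or, for plasma cells, 2. In FVB/NJ they ranged from -0.70 to 0.42 for de novo lipogenesis, -0.54 to 0.20 for glycolysis and -0.49 to 0.055 for oxidative phosphorylation, turning without water mouse 1. In the difference of FVB/NJ from C57BL/6J they ranged from -0.87 to 1.25 for B cells, -0.43 to 0.45 for antigen presentation, -0.76 to 0.40 for de novo lipogenesis, -0.44 to 0.27 for glycolysis and -0.28 to 0.25 for oxidative phosphorylation, and from DBA/2J -0.51 to -0.00053 for the last, turning without C57BL/6J fructose mouse 2 for the immune lists and without FVB/NJ water mouse 1 for the others.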

Other observations

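Further gene groups were read in the per-mouse scores. Plasma cell genes, which mark antibody-secreting cells, had a lower score on fructose in DBA/2J by an exact test (difference -0.492, exact p = 0.015), and fibroblast and preadipocyte genes a higher one (0.473, exact p = 0.019). Neither held after adjustment over the 45 marker tests, of which the lowest adjusted p was 0.29. The Y chromosome gene Eif2s3y, a translation initiation factor, was called higher on fructose in DBA/2J (log2 0.60, SE 0.16, limma adjusted p = 0.028). That call was lost with log2 depth as a covariate (0.50, SE 0.18, adjusted p = 0.33), with the liver score (adjusted p = 0.058), with 4 scores (adjusted p = 0.076) and with only DBA/2J mice (adjusted p = 0.071), and it was kept without water mice 1 and 5 (0.63, adjusted p = 0.034). Eif2s3y also lost its call in 5 of 25 fits that each left out 1 mouse.

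The share of TPM in loci of the mitochondrial chromosome on fructose and water was 0.452 and 0.502% in C57BL/6J (exact p = 0.80) and 0.462 and 0.636% in FVB/NJ (exact p = 0.30). DBA/2J water mouse 5 had 2.87 gigabases and a mean correlation of 0.818 with its own group, and water mouse 1 had 0.781. No mouse pair within a group correlated above 0.986.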
